A study of Caenorhabditis elegans with 2 samples.

How the data were processed

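Chromatin immunoprecipitation and sequencing was used to map a GFP-tagged ZK185.1 protein in the nematode Caenorhabditis elegans. Per the labels, the worms were whole hermaphrodite young adults of the transgenic strain OP474, collected 56.25 h after larvae had been synchronized at the L1 stage. The strain carries a fusion transgene of ZK185.1 with a C-terminal GFP-FLAG tag in an unc-119 mutant background, and the precipitation used an antibody against GFP. There were 2 biological replicates from separate biosamples and 1 group, so no comparison between conditions was possible. A control experiment that the labels point to, and signal tracks, were not analysed here.

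The authors deposited peak lists on the ce10 and ce11 builds, and per the manifests deposited with each library they were made as follows. A relaxed list of 30000 regions, meant as input to the irreproducible discovery rate (IDR) procedure, was called for each replicate and for the pooled reads of both replicates, each time with a control alignment. An optimal IDR-thresholded list of 2053 peaks on ce11 and 1980 on ce10 was then derived from these. Because the relaxed lists are filled to a fixed length, most of their regions are background by design, and a count of regions in them carries no information on depth. The aligner, the peak caller, their settings and the IDR threshold are not given in the sources used here. The column called signal in the deposited lists is the authors' peak height, with no stated scale. Its median was 5.58 in replicate 1, 7.96 in replicate 2 and 15.4 in the pooled list, so that it was used only to rank and describe peaks within a list or beside its replicate values. A second column holds the −log10 of a q-value, as deposited by the authors, and it was used in 1 alternative ranking. A further column gives the summit as an offset from the start of the peak. Read counts and sequencing depth are unknown from these files, and no interval here covers them.

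The thresholded list was compared with the pooled list by exact coordinates. All 2053 thresholded peaks were found there, and they were the 2053 regions with the highest signal, with a lowest signal of 57.0. Consequently the alternative of taking the same number of the strongest pooled regions returns the same peaks and tests nothing. The region ends on ce11 lay within the chromosome lengths of the WBcel235 reference in all lists, and the gene annotation was that of Ensembl release 115 on the same build. Coordinates are 1-based on ce11 throughout, and none were converted between builds. There were 9 thresholded peaks that repeated an interval with another summit, and they were kept as deposited. Columns of other samples left unused numbered 0.

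A gene start was the annotated 5′ end of the gene. The start window ran from 1000 bp upstream to 200 bp downstream of it. Trans-splicing, which is common in C. elegans, can place the annotated start downstream of the site where transcription begins. Background regions were the 27488 pooled relaxed regions with a summit over 500 bp from any thresholded summit. The replicates were compared at equal length through the 2053 strongest regions of each, and summits within 100 bp counted as shared. Overlap and start-window shares were tested against 1000 circular shifts of the summits along each chromosome with a fixed seed (rotation permutation test), for which 0.001 is the smallest p possible. The overlap test was one-sided and all others two-sided. Correlations were tested over 100000 permuted pairings, for which 1e-05 is the smallest p. Shares were tested with exact binomial tests and have exact Clopper-Pearson 95% intervals, and odds ratios are conditional estimates with exact 95% intervals from Fisher's exact test. These intervals cover counting of peaks or genes only. Genes that lie close together can share a peak, and the exact tests count them as independent, so their p-values can be too small.

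Before the data were examined, 30 gene lists, the tests, the alternatives and the naming rule were fixed. Lists were defined by symbol patterns or biotype. Protein-coding lists were compared with the other protein-coding genes and RNA lists with all other genes on the nuclear chromosomes, with Benjamini-Hochberg adjustment over the 30 lists and a threshold of 0.05. The lists overlap in part, for example where a pair of genes shares a promoter region. The microRNA list matched only 8 genes because annotated symbols carry a species prefix, and it was therefore repeated by biotype, an alternative chosen after seeing the data. Words of 6 bases, read on both strands, were scored as present or absent within 50 bp of each summit and in a flank window of the same size centred 300 bp away on a random side, and compared with an exact McNemar test adjusted over the 2080 distinct words.

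The named items were ZK185.1 and unc-119, the nearest protein-coding gene within 1000 bp (otherwise the region) of each of the 25 peaks with the highest signal, and up to 4 members with the highest signal from each list past the threshold. For words, the 5 with the smallest p among those more frequent and 3 among those less frequent were named. As 15 of the 25 strongest peaks proved to be mitochondrial, the 25 strongest nuclear peaks were described as well, which was decided after seeing the data. Alternatives covered the build, the overlap rule, the number of peaks, each replicate alone, a stricter threshold, other windows, other backgrounds, other rankings and other control windows. For the gene lists, the rotation test used the ratio of the list share to the share of all other genes, with 0.5 added to both counts. Added after seeing the data were the exclusion of mitochondrial peaks, the exclusion of peaks in tRNA start windows and the rotation test of the lists without the added 0.5.

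Calculations were done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The procedures were tested on simulated data. With rotated nuclear peaks and 46890 genes, the list test called at most 2 of 30 lists in 20 runs, with a mean of 0.75 per run. It thus made some calls where no list effect existed, and the rotation test is given beside it for that reason. It recovered 27 of 27 lists into which peaks had been planted. The word test called 0 of 2080 words in 1 run of 2034 rotated nuclear peaks and recovered 10 of 10 planted words. Rotation removes the difference in GC content between real summits and flanks, so this run cannot show how many calls come from composition. For 2053 peaks the overlap test gave a p below 0.05 in 0 of 20 unrelated pairs and returned 10.3% for a planted overlap of 10%.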

Results

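The binding of ZK185.1, described in the RefSeq annotation as a protein with a C2H2-type domain, was mapped with an anti-GFP precipitation in young adult hermaphrodites carrying a GFP-tagged copy. The data comprised 2 biological replicates of 1 group, with a relaxed list of 30000 regions for each replicate and for the pooled reads, and an optimal thresholded list of 2053 peaks on ce11. The thresholded peaks had a median width of 316 bp and a median signal of 93.7, in the authors' own unit of peak height. Sequencing depth was unknown. With no second condition, the questions addressed were which genes and regions carried peaks, where in the genome these lay, how well the replicates matched, and which sequences the sites shared.

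The tagged gene and unc-119, the gene mutated in the strain background, were examined first as a check on the labels. No thresholded peak lay within 5000 bp of ZK185.1 (WBGene00022681; chromosome IV, 4548553 to 4552788, plus strand). The pooled relaxed list had 12 regions there, of which the strongest, at 4546810 to 4547125 upstream of the gene, had a signal of 53.8 and rank 2233, just below the weakest thresholded peak. Each replicate had 14 regions in this window. The strongest was at 4548126 to 4548441 in replicate 2, immediately upstream of the annotated start, with a signal of 52.4 and rank 945, and at 4546842 to 4547171 in replicate 1, with a signal of 30.96 and rank 1161. Around unc-119 (WBGene00006843; chromosome III, 10902641 to 10908935) the thresholded, pooled and replicate 2 lists had 0 regions, and replicate 1 had 4 with signals of at most 5.47. The window around ZK185.1 was thus occupied by moderate relaxed regions in both replicates but not by a peak past the authors' threshold.

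The replicates shared far more sites than unrelated positions would. Of the 2053 strongest regions of replicate 1, 990 (48.2%) had a summit within 100 bp of a summit among the 2053 strongest of replicate 2, against a mean of 0.676% after rotation (one-sided rotation permutation test, p = 0.001, the smallest possible). Among thresholded peaks, 86.7% were matched in the full relaxed list of replicate 1, 93.2% in that of replicate 2 and 80.7% (1656 peaks) in both. Across these 1656 peaks the signals of the replicates were correlated, with a Spearman rho of 0.525 and a Pearson r of 0.594 on the log2 scale (permutation p = 1e-05 for each, the smallest possible). This correlation is across peaks, which are not independent replicates. The median ratio of the replicate 2 to the replicate 1 signal was 1.51, on scales that need not be the same.

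**Figure D1:**
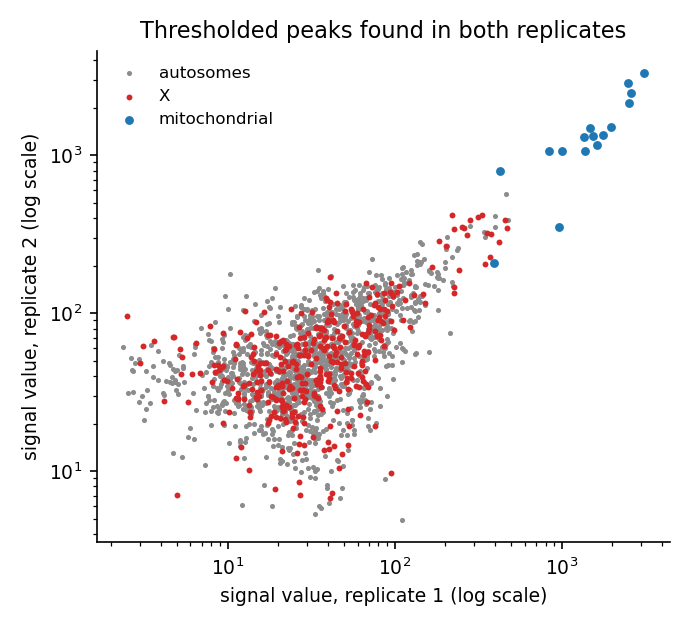
Signal value of each thresholded peak in replicate 1 (x axis) against replicate 2 (y axis), both on log scales, for the 1656 peaks matched in both; grey points are autosomal, red points lie on X and blue points on the mitochondrial genome. The mitochondrial points occupy the upper right corner, and the points spread more widely at low signal.

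The highest peaks of the list were on the mitochondrial genome, which held the 15 strongest peaks and 19 in all. The strongest, at 12152 to 12755 within the coding exon of WBGene00010967, had a signal of 6311 and rank 1 in both replicates, and the next, at 9911 to 10383 in the coding exon of WBGene00010965, had 5268. A peak with a signal of 3376 had its summit 521 bp upstream of the start of COX3, a cytochrome c oxidase subunit gene. Another, 333 bp downstream of that start, had 2421. A further peak, 167 bp downstream of the start of ND1, a complex I subunit gene, had 1837. Together the mitochondrial peaks covered 54.3% of that genome's 13794 bp, while nuclear peaks covered 0.504% of the nuclear genome. The median signal of the mitochondrial peaks was 2421, against a highest nuclear signal of 1039. The pooled relaxed list also held 19 mitochondrial regions, so the threshold did not separate regions there. Whether these peaks reflect binding of the tagged protein was not tested.

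The 2 strongest nuclear peaks lay just upstream of genes for ribosomal proteins of the large subunit, and 6 of the 10 strongest lay on X. The peak 290 bp upstream of rpl-3 (chromosome III, 3867399 to 3867706) had a signal of 1039 in the pooled data, 466 in replicate 1 and 570.5 in replicate 2. Next came the peak 340 bp upstream of rpl-15 (chromosome IV, 654779 to 655061), with 886 and replicate values of 478 and 392. The fifth, at chromosome IV, 4749904 to 4750208, with a signal of 827, lay between the divergent genes Y17G9B.5 and rpl-20, 179 bp upstream of the former and 283 bp upstream of the latter. Further peaks of this kind lay 53 bp upstream of tasp-1 (signal 754), 153 bp upstream of cdc-48.1, which encodes an AAA ATPase of protein quality control (706), 442 bp upstream of rpl-35 (698), 20 bp downstream of the start of cux-7 (663), 527 bp upstream of K12H4.5 (524) and 285 bp upstream of cox-5A, a cytochrome c oxidase subunit gene (519). The peak at chromosome II, 5844658 to 5845215 (signal 536), was nearest to ZK1248.17 among protein-coding genes and lay 38 bp upstream of sls-2.1, an SL2 spliced leader RNA gene.

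A separate set of very strong peaks lay on X, mostly away from gene starts. The intergenic regions at X 11093868 to 11094436 and X 16681845 to 16682297 had signals of 836 and 832, with their summits 4010 and 2551 bp downstream of the nearest protein-coding start. Others were intergenic at X 13700612 to 13701095 (760) and X 12362868 to 12363495 (739.5), in an intron of mom-1 at X 6296319 to 6296899 (754.5) and in an intron of Y41G9A.17 at X 2996849 to 2997404 (735). Closer to starts were the peaks 669 bp upstream of the insulin-like gene ins-39 (618), 773 bp upstream of nspc-17 (595) and 994 bp upstream of fbxb-58 (545). Among the 100 strongest nuclear peaks, 5 of 25 on X (20%) lay in the start window of a protein-coding gene, against 60 of 75 on autosomes (80%; odds ratio 0.0649, 95% interval 0.01625 to 0.214, Fisher's exact test p = 1.17e-07, a test chosen after seeing the data). The median width of these X peaks was 484 bp, and that of the autosomal peaks 247 bp.

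Genes of the translation apparatus and of energy metabolism carried peaks at their starts far more often than other genes. Of 19973 nuclear protein-coding genes, 1352 (6.77%) had a thresholded summit in their start window. In the list of cytosolic ribosomal proteins, 51 of 82 genes (62.2%) had a peak, against 6.54% of other genes (odds ratio 23.5, 95% interval 14.7 to 38.1, Fisher's exact test with Benjamini-Hochberg adjusted p = 3.35e-38). The odds ratio was 11.85 when each peak counted only for its nearest start. The 51 genes with a peak comprised 30 of 47 of the large subunit, 20 of 31 of the small subunit and 1 of 4 others. Those of the large subunit were led by rpl-3, rpl-15, rpl-20 and rpl-35. In the oxidative phosphorylation list 20 of 44 genes had a peak (45.5%, odds ratio 11.6, exact test adjusted p = 6.52e-12), the strongest being at cox-5A (519), at atp-1 and atp-5, which encode ATP synthase subunits (327.5 and 298), and at cox-6A (264). Translation factors had peaks at 11 of 40 genes (odds ratio 5.26, exact test adjusted p = 0.000146), led by iff-2 (317.5) and the elongation factor genes eef-1G (280), eef-1B.1 (261) and eef-1A.1 (245). The call for translation factors was lost in the rotation permutation test, which keeps the spacing of peaks (adjusted p = 0.0649), and their odds ratio was 9.93 with replicate 2 alone (without replicate 1).

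Lists for RNA splicing, protein folding, protein turnover and organelle upkeep were also over-represented. Spliceosome genes had peaks at 11 of 32 starts (odds ratio 7.26, exact test adjusted p = 1.50e-05), including prp-19 (389), rsp-6 (174) and a peak between the divergent genes rsp-1 and rsp-2 (164). Chaperone genes had peaks at 16 of 59 (odds ratio 5.17, exact test adjusted p = 5.19e-06), led by hsp-60 (466), the chaperonin genes cct-8 (443) and cct-1 (331), and dnj-13 (331). Calls with less margin were made by the exact test for the vacuolar ATPase (6 of 20, odds ratio 5.92, adjusted p = 0.00404; vha-13, 137), the proteasome (6 of 33, odds ratio 3.07, adjusted p = 0.0384; rpn-3, 216) and mitochondrial ribosomal proteins (12 of 70, odds ratio 2.87, adjusted p = 0.00556; mrpl-23, 335). With replicate 1 alone (without replicate 2), those last 3 lists did not pass, with adjusted p of 0.373, 0.0876 and 0.279 and odds ratios of 1.76, 2.83 and 1.76. In the rotation permutation test their adjusted p was 0.315, 0.494 and 0.292. When each peak counted only for its nearest start, chaperones missed the threshold (odds ratio 2.56, exact test adjusted p = 0.0589) and the odds ratio of spliceosome genes was 4.39.

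Genes for small structural RNAs also stood out, though against another background than the coding lists. All other genes here include 15363 piRNA genes, of which 0.937% had a peak. This lowers the share of other genes and raises the odds ratios. A summit lay in the start window of 357 of 612 tRNA genes (58.3%), against 4.83% of all other genes (odds ratio 27.6, 95% interval 23.3 to 32.7, Fisher's exact test with Benjamini-Hochberg adjusted p = 3.74e-285). The strongest of these lay on X at 3035926 to 3036310, between the divergent tRNA genes WBGene00023110 and WBGene00023111, with a signal of 673. On X 201 of 276 tRNA genes had a peak (72.8%), and on the autosomes 156 of 336 (46.4%; odds ratio 3.09, Fisher's exact test p = 3.51e-11, chosen after seeing the data). Clustered tRNA genes share peaks, as 309 peaks lay in the windows of the 357 genes and 168 in those of the 201 on X. The exact tests count such genes as independent. In the rotation permutation test tRNA genes had an adjusted p of 0.00856. Genes for snRNAs and snoRNAs had a peak at 129 of 475 starts (27.2%, odds ratio 6.65, exact test adjusted p = 4.21e-52). Some of these share a peak with a coding gene, including 3 of the 4 with the strongest peaks. The snoRNA or snRNA genes K11H12.13 and K11H12.12 lie within rpl-15 on its strand, 555 and 886 bp from the rpl-15 peak. C06A1.9 was counted through the cdc-48.1 peak, 496 bp away. Such counts cannot be told apart from peaks of the coding genes.

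**Figure D2:**
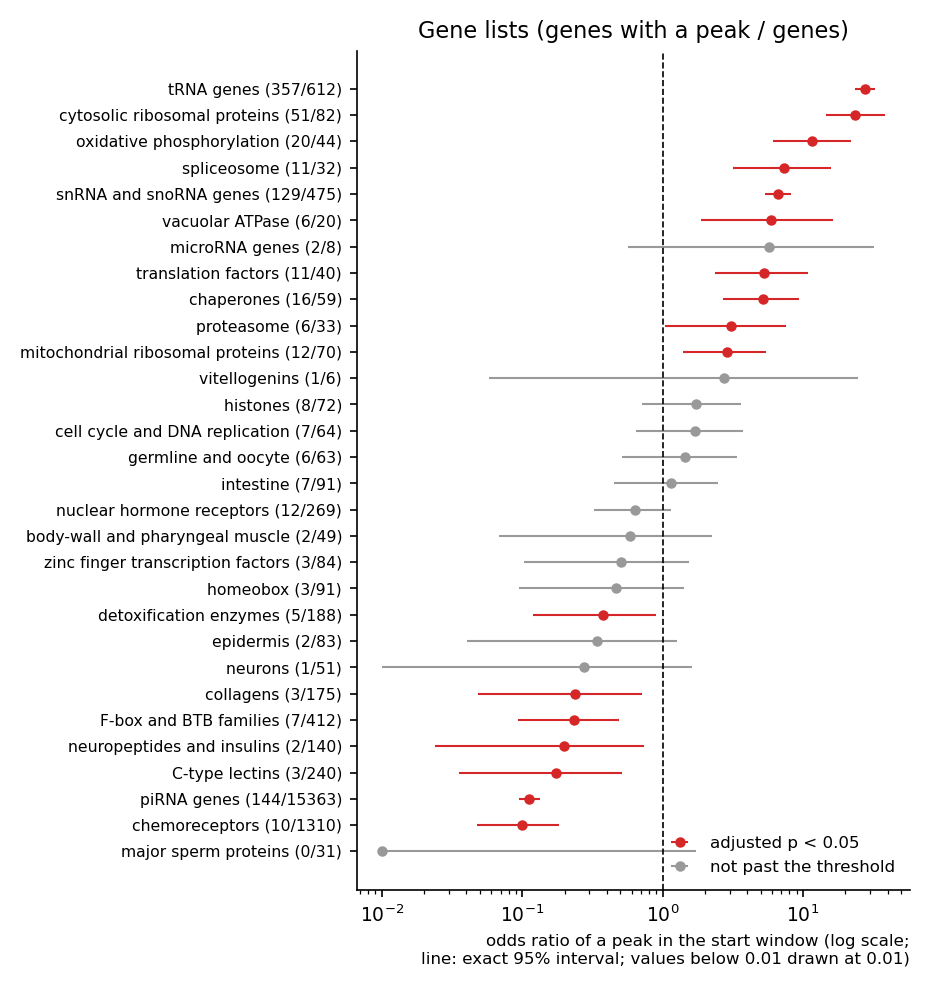
Odds ratio of carrying a thresholded summit in the start window for each of the 30 gene lists (log x axis; points are estimates, lines exact 95% intervals), with the genes with a peak and all genes of the list in brackets; red lists passed the adjusted threshold and grey lists did not. tRNA genes (357/612) and cytosolic ribosomal proteins (51/82) lie furthest to the right, and chemoreceptors (10/1310) and piRNA genes (144/15363) far to the left.

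Of the 30 lists, 17 passed the threshold, 10 with more peaks than other genes and 7 with fewer. The under-represented lists were large gene families. Only 10 of 1310 chemoreceptor genes had a peak (0.763%, odds ratio 0.0993, exact test adjusted p = 2.11e-27), among them sre-23 (260) and srd-44 (176). piRNA genes had 144 of 15363 (odds ratio 0.112, exact test adjusted p = 5.93e-262), with the strongest, 21ur-12279, at the atp-1 peak. C-type lectins had 3 of 240 (odds ratio 0.1725, exact test adjusted p = 0.000225; clec-126, 115) and F-box and BTB family genes 7 of 412 (odds ratio 0.234, adjusted p = 8.68e-06; fbxb-58, 545). Collagens had 3 of 175 (odds ratio 0.2385, exact test adjusted p = 0.00784; col-185, 207), neuropeptides and insulins 2 of 140 (odds ratio 0.198, adjusted p = 0.0124; ins-39, 618) and detoxification enzymes 5 of 188 (odds ratio 0.374, adjusted p = 0.0357; gst-27, 321). Part of this also held for the weaker background regions among genes without a thresholded peak. There the odds ratio was 0.381 for chemoreceptors, 0.3145 for C-type lectins and 0.427 for F-box and BTB families. It was 0.465 for neuropeptides and insulins and 0.657 for piRNA genes, but 0.993 for collagens and 1.69 for detoxification enzymes. Without replicate 1 the collagen odds ratio for thresholded peaks was 0.551 with an adjusted p of 0.194, and that of C-type lectins was 0.110. In the rotation permutation test collagens, neuropeptides and insulins, detoxification enzymes and F-box and BTB families did not pass, with adjusted p of 0.106, 0.193, 0.363 and 0.0649, and without the 0.5 added to each count C-type lectins did not pass either (adjusted p = 0.174).

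Lists of tissue and stage markers did not pass the threshold. The counts were 8 of 72 for histones, 7 of 64 for cell cycle and DNA replication, 6 of 63 for germline and oocyte, 7 of 91 for intestine, 2 of 49 for muscle, 1 of 51 for neurons, 2 of 83 for epidermis, 1 of 6 for vitellogenins and 0 of 31 for major sperm proteins, whose odds ratio has an upper bound of 1.74. The same held for lists of regulators, with 12 of 269 nuclear hormone receptors, 3 of 91 homeobox genes and 3 of 84 zinc finger transcription factors. The symbol pattern of the last list also matches the zip genes, which encode bZIP proteins. Without replicate 1, cell cycle and DNA replication passed with an odds ratio of 3.41 and an adjusted p of 0.000963, and with the 2000 bp window intestine (odds ratio 1.95, exact test adjusted p = 0.04225) and microRNA genes (odds ratio 7.39, adjusted p = 0.0297) passed. Major sperm proteins passed in the rotation permutation test with 0.5 added to each count (ratio 0.238, adjusted p = 0.00856), but 527 of the 1000 rotations also had 0 of these genes, and without the added 0.5 the adjusted p was 1. microRNA genes had peaks at 2 of the 8 matched by symbol (adjusted p = 0.114) and at 20 of 261 matched by biotype (odds ratio 1.42, unadjusted Fisher's exact p = 0.134). The background of both includes the piRNA genes.

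Peaks were concentrated just upstream of coding genes. A summit fell in the start window of a protein-coding gene for 1050 of 2053 peaks (51.1%, exact 95% interval 49.0 to 53.3), against a mean of 21.6% after rotation (rotation permutation test, p = 0.001, the smallest possible). Of the background regions 25.7% did so (odds ratio 3.03, 95% interval 2.765 to 3.32, Fisher's exact test p = 3.42e-123). Of the summits within 500 bp of the nearest start, 784 of 922 (85.0%, interval 82.6 to 87.3) lay upstream of it (exact binomial test against 50%, p = 2.73e-110), at a median position of -168 bp. Coding exons outside start windows held 5.70% of summits, against 19.97% after rotation, and introns 18.8% against 30.4% (rotation permutation tests, p = 0.001 for each). Of the places left, RNA genes and pseudogenes held 4.82% against 3.245% (rotation permutation test, p = 0.002), intergenic regions 15.9% against 21.7% (p = 0.001) and untranslated exons 3.65% against 3.07% (p = 0.140).

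The strongest 25% of peaks lay in start windows more often than the weakest 25%, at 59.6% against 42.1% of 513 peaks each (odds ratio 2.03, Fisher's exact test p = 2.52e-08). This depended on the ranking. With peaks ranked by their mean rank in the replicates, the odds ratio was 1.65 (Fisher's exact test p = 0.000474). When peaks were ranked by the authors' q-value column and then by signal, the odds ratio was 0.810 (p = 0.104). That column ran against the signal within the thresholded peaks, with a Spearman rho of -0.262 across peaks, although it rose with signal across the pooled list (rho 0.9995) and across its regions away from thresholded peaks (rho 1). How it was computed was unknown.

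**Figure D3:**
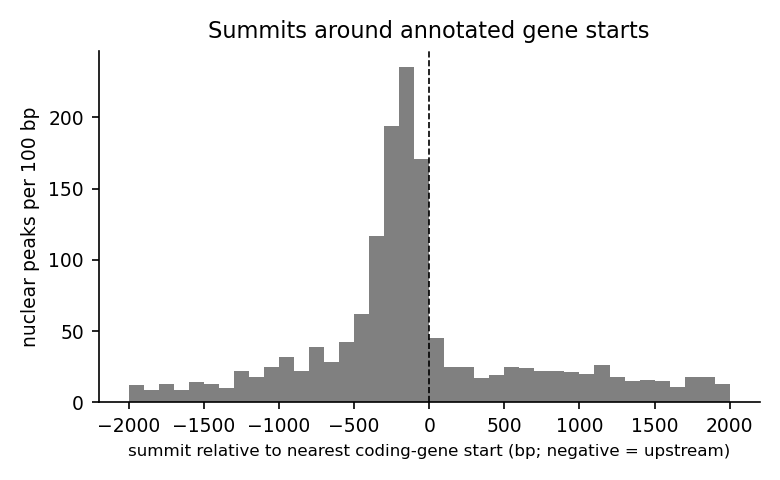
Number of nuclear thresholded summits (y axis, per 100 bp) by position relative to the nearest protein-coding gene start (x axis, bp, negative values upstream), for the 1502 of 2034 peaks within 2000 bp. The fullest bin, from -200 to -100 bp, holds 235 summits, and the count drops at the start itself.

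Chromosome X carried the most peaks. It held 459 of 2034 nuclear peaks (22.6%, exact 95% interval 20.8 to 24.45), against 17.7% of nuclear length (exact binomial test, p = 2.25e-08), and 25.9 peaks per Mb compared with 15.5 on chromosome V and 23.7 on chromosome III. tRNA start windows held 168 of the X peaks (36.6%) and 141 of 1575 autosomal peaks (8.95%; odds ratio 5.865, Fisher's exact test p = 4.05e-41). Outside tRNA windows, the X share was 16.9% (interval 15.1 to 18.7, exact binomial test p = 0.394), no longer above the share of length. That interval still lay above the 13.67% of protein-coding starts found on X, so the excess was lost only against length. For peaks in the start windows of coding genes, the X share was 15.94% (interval 13.76 to 18.3), only narrowly above 13.67%. Start windows of coding genes held 35.9% of X peaks and 55.2% of autosomal peaks (odds ratio 0.455, Fisher's exact test p = 3.945e-13). The comparisons by class of peak were chosen after seeing the data. On the autosomes, 73.2% of summits lay in the middle 50% of the chromosome (exact binomial test, p = 1.90e-78), which also exceeded the 55.7% of protein-coding starts found there.

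**Figure D4:**
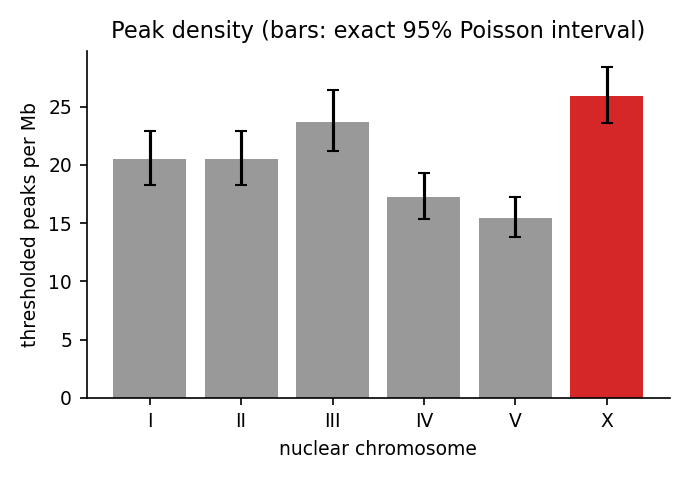
Thresholded peaks per Mb (y axis) on each nuclear chromosome (x axis), with exact 95% Poisson intervals as error bars and X in red. X has the highest density, 25.9 per Mb, and chromosome V the lowest, 15.5 per Mb.

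Summits shared GA-rich and GACGCAG-like words. GAGAGA (or its complement) was present within 50 bp of 21.2% of summits and in 5.845% of flank windows (exact McNemar test with Benjamini-Hochberg adjusted p = 2.48e-46), and the overlapping word AGAGAG in 17.1% against 4.43%. The difference for GAGAGA and AGAGAG, 15.4 and 12.7 percentage points, was 9.69 and 6.77 with replicate 1 alone (without replicate 2). It was 14.4 and 13.3 with replicate 2 alone (without replicate 1). AGACGC was present at 12.3% against 2.48% (exact test adjusted p = 4.64e-32), ACGCAG at 13.1% against 3.02% and AGAGAC at 15.8% against 4.63%. In all, 628 of 2080 words were more frequent at summits and 408 less frequent. The latter were led by AAAAAT (23.8% against 46.4%), AAAATT (17.5% against 38.5%) and TAAAAA (13.4% against 30.9%). The mean GC content was 45.6% in nuclear summit windows (SD 7.81 across 2034 windows), 35.7% in their flanks and 36.4% in background regions, so that many words differ together with composition. The difference in GC content was not removed from the word test.

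**Figure D5:**
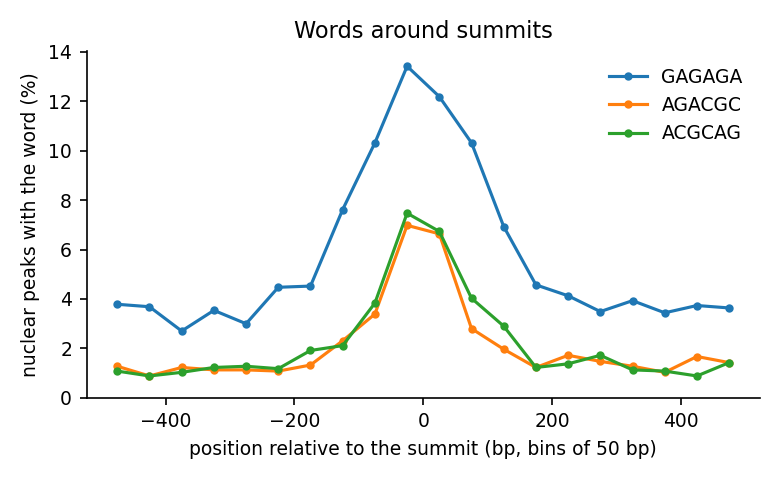
Share of the 2034 nuclear peaks (y axis, %) with GAGAGA, AGACGC or ACGCAG on either strand in each 50 bp bin around the summit (x axis, bp). GAGAGA reaches 13.4% in the bin from -50 to 0 bp, and all curves fall with distance from the summit.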

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

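The comparison of X with relaxed regions was chosen only after the result had been seen. The use of the spread between replicates at the ZK185.1 locus and of the interval over resampled lists was also added after those results had been seen, and the 2 single values, 89.1 and 0.492, lay on the side of the bounds set in advance that counts against the explanations. The thresholded list held 19 peaks on the mitochondrial genome, which the comparisons of chromosomes, gene lists and chromosome centres did not use. Of these, 17 were matched in replicate 1 and 17 in replicate 2, with signals of up to 3096 and 3313.

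The relaxed regions around the tagged ZK185.1 locus form a first pattern to weigh. Extra copies of the locus carried by the transgene would raise signal broadly across it, unless the control alignment used in calling carried them too. That control was not examined here, so a low value could not exclude extra copies. The summed signal in a 40 kb window there was 697, 2.96 times the median of 2503 such windows, and lay at percentile 89.1, below the bound of 95 set in advance. The replicates lay on either side of that bound, at 95.3 in replicate 1 and 90.65 in replicate 2, so that the explanation stays open. No biological explanation was tested, since the design has no second group.

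The over-represented gene lists could come from a general enrichment at active starts that any region list of these libraries shows. Among genes without a thresholded peak, the median log2 odds ratio of the 10 lists for weaker relaxed regions was 1.30, which is 0.492 of the 2.65 for thresholded peaks. The 95% interval of that ratio over resampled lists, 0.327 to 0.737, includes the bound of 0.5 set in advance, so that a general enrichment may account for part of the pattern. In 8 of the 10 lists the interval for relaxed regions lay above 1. An untagged control precipitation was not used here, and no biological explanation was tested.

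The excess of peaks on X is a further pattern. Without peaks in tRNA start windows the X share was 16.9%, against 17.7% of nuclear length and 13.7% of protein-coding starts. The excess over length may therefore come from the many tRNA genes on X that carry peaks. An excess over coding starts remained, but it was narrow for peaks in coding start windows (15.94%, interval 13.76 to 18.3, against 13.67%). Among peaks outside the start windows of coding, tRNA, snRNA and snoRNA genes, the X share was 21.7%. The exact binomial test against 17.7% of nuclear length gave p = 0.00602. That length includes the windows left out, so the test cannot decide whether X held an excess of such peaks. They made up 32.7% of X peaks and 34.3% of autosomal peaks (odds ratio 0.9305, Fisher's exact test p = 0.538). An excess of X in any region list of these libraries stays open, because the relaxed, non-thresholded regions had an X share of 20.45% (interval 19.98 to 20.9), which overlaps the interval of the thresholded share, although the direct comparison gave an odds ratio of 1.13 (Fisher's exact test, p = 0.0248).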

How the results depend on the processing

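The settings without mitochondrial peaks, without tRNA windows, with microRNAs by biotype and with no 0.5 added in the rotation test were chosen after seeing the data. Of 71 alternatives for the main results, 65 kept the direction and side of the threshold or stayed within 1.5 times the main count. The alternative that takes the 2053 strongest pooled regions is counted among these, but it returns the same peaks and says nothing on stability.

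The X share fell to 16.9% without peaks in tRNA start windows, turning its direction against the share of length. These windows hold 168 of 459 X peaks. The odds ratio of strong against weak peaks turned to 0.810 when ranked by q-value. That column falls with signal among thresholded peaks, but whether this causes the turn was not tested. Lists past the threshold numbered 11 for the stronger 50% of peaks, which has fewer peaks, and 10 in the rotation test (8 without the added 0.5), against 17; the cause of the latter was not tested. Around ZK185.1, 4 pooled regions lay within 1 kb, against 12 within 5000 bp, because the window is smaller.

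Replicate overlap ranged from 36.5% with 2 times as many peaks to 58.35% for intervals sharing at least 1 bp. With either replicate alone, the X share was 20.2% to 21.4%, the centre share 68.8% to 69.9%, the share in start windows 45.35% to 52.6%, the upstream share 79.7% to 86.4%, the lists past the threshold 14 to 17 and the words 487 to 647. Overlap and correlation need both replicates and were not run with either left out. The lists for cytosolic ribosomal proteins, oxidative phosphorylation, spliceosome, chemoreceptors, tRNA, snRNA and snoRNA, and piRNA kept their calls in 9 of 9 alternatives. Chaperones and C-type lectins did so in 8 of 9, translation factors and F-box and BTB families in 7, collagens in 4 and the others in 5. The 8 named words kept theirs in 9 of 9. Each 9 includes the alternative that returns the same peaks, and that of the lists includes both forms of the rotation test. Sequencing depth was unknown, so its limits on weak sites could not be assessed.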

Other observations

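The comparisons by class of peak, the 8-base words and the motif counts beyond the 100 strongest peaks were chosen after seeing the data. Peaks in tRNA start windows and other peaks carried different 8-base words. CTGAGCTA was present within 50 bp of the summit at 66 of 309 peaks in tRNA windows (21.4%) and at 0 of 1725 other nuclear peaks, and GCTCTACC at 52 (16.8%) and 10 (0.580%). Read on the other strand, the former resembles the internal promoter (A box) of tRNA genes, which lies within the gene itself. AGACGCAG showed the opposite division, with 2 peaks in tRNA windows (0.647%) and 138 other peaks (8.00%), and CTAGGCCA likewise, with 2 and 64 (3.71%). Among peaks away from start windows of coding and small RNA genes, GAGAGA was present at 184 of 690 (26.7%), and it was present at 5 of 49 peaks (10.2%) in ribosomal protein windows.

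The median signal differed by class of peak. It was 150.5 for 49 peaks in ribosomal protein windows (25th to 75th percentile 94.4 to 233), 116 for 309 in tRNA windows, 99.6 for 917 in other coding start windows and 76.55 for 690 away from all of these.

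The strong X peaks away from gene starts prompted a hypothesis, that they are sites carrying the recruitment motif of the X dosage compensation complex, which binds both X chromosomes of hermaphrodites. The published consensus TCGCGCAGGGAG was searched within 100 bp of each summit with up to 2 mismatches, and the prediction was written before the search. Among the 100 strongest nuclear peaks, 13 of 25 on X (52%) and 1 of 75 on autosomes (1.33%) carried it (odds ratio 74.85, 95% interval 9.74 to 3449, Fisher's exact test p = 8.93e-09), against 0% of windows 300 bp to the side. Of the 12 X peaks without it, 7 lay in tRNA windows, 1 in a coding start window and 4 in neither, among them X 13700612 to 13701095 and X 12362868 to 12363495, with signals of 760 and 739.5. The motif thus does not cover all strong X peaks. Outside coding start windows, the set that the hypothesis names, 10 of 20 of these X peaks and 0 of 15 autosomal peaks carried it. The predicted difference was thus found, for a part of the strong X peaks.

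Among the other nuclear peaks the difference was smaller, with 12 of 434 on X and 11 of 1500 on autosomes (odds ratio 3.85, Fisher's exact test p = 0.00165). Motif-bearing peaks included X 11093868 to 11094436, X 16681845 to 16682297 and X 4208974 to 4209509, with signals of 836, 832 and 684, and the ins-39, nspc-17 and fbxb-58 peaks named above lie at motif-bearing sites. Leaving out all motif-bearing peaks changed the X share only to 21.7% (interval 19.9 to 23.6), so that the motif concerns the strongest peaks rather than the excess of X as a whole. Whether ZK185.1 itself binds there, or whether these sites are recovered in precipitations of other tagged proteins too, was not tested.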
